A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

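The deposited table gives 1 column of values for each of 12 RNA sequencing samples of budding yeast, 3 for each of wild type, sac3∆, R288D and cdk8∆. Per the labels, cells were grown in synthetic medium without leucine, RNA was extracted with hot phenol, DNA was digested, ribosomal RNA was depleted and libraries were made with a kit. Whether replicates were separate cultures, and the strand setting of the counting, are not given in the sources used here. The authors' processing notes name TopHat2 2.0.9, HTSeq 0.5.4p3, R 3.0.1, edgeR, limma and the R64 build, without saying which of them made the values. The deposited values are RPKM, read density per exon length and library size. Library sizes appear scaled between samples, which was inferred here from the values.

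The unit was checked from the values. For features with an exon length in the reference, value times length fell on whole multiples of 1 step per sample, and 99.34 to 99.67% of values under 300 reads were whole within 0.1 read. Those steps give 16.18 to 22.44 M reads (mega-reads) per sample and scaled library sizes 0.864 to 0.892 times the recovered reads in wild type, 0.969 to 0.999 in sac3∆, 0.967 to 0.991 in R288D and 1.14 to 1.18 in cdk8∆. The 10 most abundant features took 13.07 to 13.99% of reads in cdk8∆ and 15.47 to 17.22% elsewhere. The table holds 7126 features, of which 6162 matched the R64 annotation and 964 did not. Listed at 0 in every sample were 305 features, among them 14 of 14 ribosomal RNA and 28 of 28 mitochondrial features matched to the annotation, and 468 to 651 features were at 0 in a given sample.

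Values were taken as log2 of RPKM plus a pseudocount of 1, and the 6124 features with a mean of at least 1 RPKM over the 12 samples were tested. Of these, 369 had no reference entry. A model with a mean per group (8 residual degrees of freedom) was fitted to all 12 samples with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a mean trend), two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Each mutant was compared with wild type and with each other mutant. The adjusted p-values measure only the spread between samples, and groups of 3 were not tested for outliers. Errors of log2 changes are limma standard errors (median 0.0734), and a call is a feature past the threshold. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

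A total of 39 gene lists was fixed, and 37 had members to test: TREX-2, Mediator kinase, other Mediator, THO, TREX and export, and SAGA subunits; the galactose, phosphate and iron regulons, glucose-repressed genes and hexose transporters; general stress, heat shock, oxidative stress, multidrug resistance, DNA damage, cell wall integrity, and aerobic repression with seripauperin genes; Gcn4-linked, sulfate and methionine, purine, nicotinate and thiamine, ergosterol and phospholipid synthesis; ribosomal proteins, ribosome biogenesis, glycolysis, TCA cycle and respiratory chain; flocculins, early meiosis, a-cell and alpha-cell markers, pheromone response, auxotrophic markers, cyclin, S phase and histone genes, mitotic genes, and small nuclear and nucleolar RNAs. Ty elements and mitochondrially encoded genes had no tested member. Members were counted by adjustment over all features and over the list alone. Each list was tested with limma camera at a preset correlation of 0.01, adjusted over 111 results (37 lists in 3 comparisons with wild type), and again with the correlation estimated from the data. Of 55 camera calls, 6 held with an estimated correlation. The same tests between mutants, adjusted separately, and the median of the 5 non-member genes nearest in abundance to each member were added after the data were seen. Each such gene was counted once, so the 139 ribosomal protein genes had 278 matched genes.

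Genes were named by a fixed rule. Named were SAC3, SSN3 and the other members of their complexes, and, in each comparison with wild type, the 10 largest rises and 10 largest falls among called genes whose 3 mutant values all lie beyond all 3 wild type values. SAC3, SSN3, genes without a standard symbol, Ty elements, mitochondrially encoded genes and non-coding RNAs were left out of that ranking. Named by the same ranking were the 5 largest differences in each direction between mutants. Added were the 5 genes with the largest smallest rise and fall among those called in all 3 mutants, and from each list up to 4 called members with the lowest adjusted p. Gene lists, comparisons, tests, the naming rule and the alternatives were fixed before the data were examined.

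Overlap between mutants was set against the count given by independent calls and against 100 simulations with no effect in which the wild type samples are shared. Alternatives chosen at that time were pseudocounts of 0.1 and 5, no filter, a filter at 10 RPKM, the median of all genes set equal, quantile normalization, only the groups compared, no mean trend, limma array weights, replicate number as a block, each replicate left out, an added 2-fold threshold, an adjusted p of 0.01 and the estimated camera correlation. Added after the data were seen were limma-voom on the recovered reads (5755 genes), the same genes in limma, quantile normalization before camera and for the count of genes changed in all 3 mutants, and a list of zinc genes with and without ZPS1, ZRT1 and ADH4. Added likewise were the estimated correlation after quantile normalization and the abundance trend with the inferred scaling undone or RPKM medians set equal. Replicate numbers did not pair samples: of 18 correlations of residuals between samples of like number, 2 exceeded 0.1, and 2 of 12 samples correlated best with one of their own number.

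The procedure was tested on simulated data of the depth of sac3∆ and wild type, with 50 genes altered at each size among 5750. It recovered 26% of genes at 1.25-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 10 of 165 calls were false (6.06%). Pearson's r between samples was 0.988 to 0.996 within groups and 0.942 to 0.992 between groups. Because the strand setting is unknown, values of overlapping and antisense genes are uncertain, as are those of near-identical genes such as the COS, seripauperin, hexose transporter and paired ribosomal protein genes. Count-based tests in edgeR were not used here, since the table holds no counts, and the recovered reads entered only the limma-voom alternative.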

Results

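RNA sequencing of budding yeast (Saccharomyces cerevisiae) gave transcript levels in 12 samples, 3 in each of 4 groups. SAC3 encodes the scaffold of TREX-2, the complex that links transcription to mRNA export at nuclear pores, and SSN3 (CDK8) encodes the kinase of the Mediator kinase module. The wild type group was a sac3∆ strain carrying 13MYC-tagged SAC3 on a plasmid. The sac3∆ group was a sac3∆ strain with the empty plasmid, the R288D group was a sac3∆ strain with plasmid SAC3 bearing the R288D substitution, and the cdk8∆ group had the empty plasmid and its native SAC3. The depth recovered from the table was 21.29, 16.29 and 17.92 M reads (mega-reads) for the wild type replicates, 17.24, 19.87 and 17.4 for sac3∆, 17.18, 16.18 and 17.66 for R288D and 21.82, 17.96 and 22.44 for cdk8∆. Values are RPKM, as mean ± SD (n = 3), and changes are log2 ratios of RPKM plus 1 with the limma standard error, so changes of scarce genes are understated.

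SAC3 (YDR159W, chromosome IV, 771877 to 775782, plus strand in the R64 build, 1 exon) lay at 51.3 ± 2.32 RPKM in wild type and at 0.0458 ± 0.0416 in sac3∆. The R288D group held 63.7 ± 1.18 RPKM of SAC3, a log2 change of 0.31 ± 0.06 from wild type (limma adjusted p = 6.85e-04) that was no longer called with a pseudocount of 0.1. In cdk8∆, where SAC3 is native, it lay at 33.5 ± 0.347 RPKM, a change of -0.60 ± 0.06 (limma adjusted p = 2.53e-06). SSN3 (YPL042C, chromosome XVI, 473040 to 474707, minus strand, 1 exon) lay at 0.205 ± 0.0816 RPKM in cdk8∆, against 49.7 ± 0.0660 in wild type, 47.8 ± 3.23 in sac3∆ and 56.9 ± 3.67 in R288D. Each of the 12 samples thus held the transcript levels that its label calls for at both deleted genes.

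**Figure D1:**
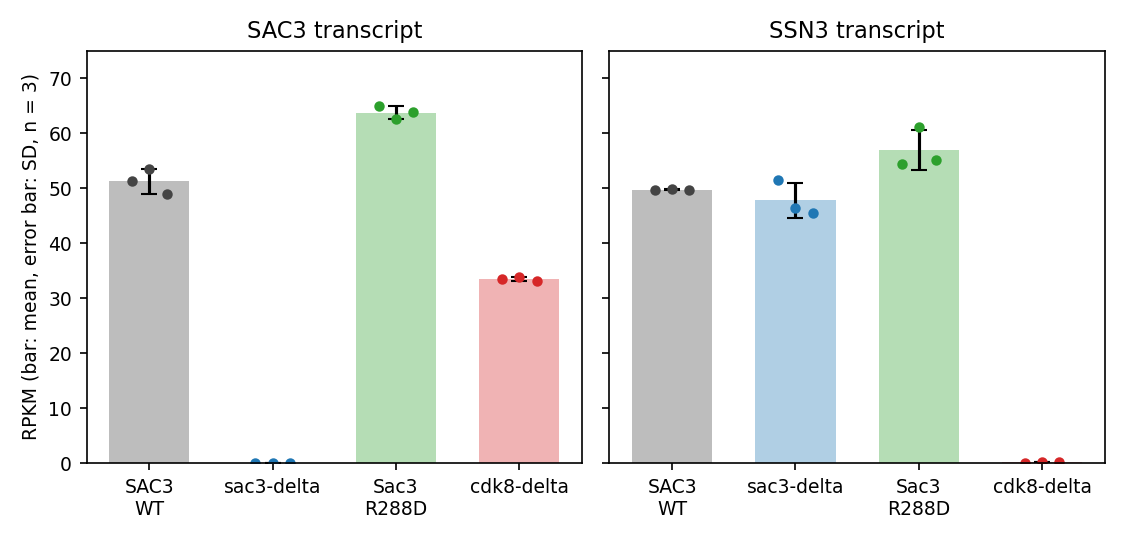
RPKM of SAC3 and SSN3 in the 4 groups, with bars for the mean, error bars for the SD (n = 3) and a point per sample. SAC3 is near 0 only in sac3∆, and SSN3 is near 0 only in cdk8∆.

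Transcripts of the other TREX-2 and kinase module subunits were compared in each mutant. CDC31, the yeast centrin, rose by 0.73 ± 0.11 in sac3∆ and 0.45 ± 0.11 in R288D (limma adjusted p = 1.67e-04 and 0.00475) and stood at 0.12 ± 0.11 in cdk8∆, which did not pass. THP1, a PCI-domain subunit, rose by 0.19 ± 0.06 in sac3∆ and 0.24 ± 0.06 in R288D, while SEM1, shared with the proteasome, changed by -0.22 ± 0.07, -0.23 ± 0.07 and -0.52 ± 0.07 in sac3∆, R288D and cdk8∆. SUS1, shared with SAGA, rose by 0.23 ± 0.08 in cdk8∆, though its difference between sac3∆ and cdk8∆ did not pass (limma adjusted p = 0.0710). In the kinase module, SRB8 (Med12) rose by 0.30 ± 0.05, 0.29 ± 0.05 and 0.47 ± 0.05 in the same order, and SSN8 (cyclin C) rose by 0.36 ± 0.07 in cdk8∆. SSN2 (Med13) rose by 0.20 ± 0.06 in R288D and 0.18 ± 0.06 in cdk8∆, and SSN3 rose by 0.19 ± 0.07 in R288D. Values that did not pass were THP1 at 0.02 in cdk8∆, SUS1 at 0.06 in sac3∆ and -0.03 in R288D, SSN8 at 0.00 and -0.16, and SSN2 at 0.10 and SSN3 at -0.06 in sac3∆. The calls of THP1, SEM1, SUS1, SSN2 and SSN3, and that of CDC31 in R288D, ended under at least 1 alternative setting.

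The comparison of sac3∆ with wild type asks which transcripts depend on the TREX-2 scaffold. The largest falls were in ZPS1 and ZRT1, genes induced under zinc limitation, of which ZRT1 encodes the high-affinity zinc transporter. ZPS1 (YOL154W, chromosome XV, 34658 to 35407, plus strand) lay at 9.48 ± 0.552 RPKM against 464 ± 17.2 in wild type (-5.47 ± 0.14), and ZRT1 (YGL255W, chromosome VII, 20978 to 22108, plus strand) at 47.9 ± 3.44 against 993 ± 37.7 (-4.35 ± 0.07). The largest rise was in FIG1 (YBR040W, chromosome II, 316968 to 317864, plus strand), which acts in mating, at 18.3 ± 1.59 RPKM against 0.784 ± 0.101 (3.44 ± 0.10). AGA1 and AGA2, the subunits of the a-agglutinin, rose by 2.62 ± 0.11 and 2.07 ± 0.06, and MFA1, which encodes a-factor, by 2.17 ± 0.21.

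The other genes among the 10 largest rises were the cell fusion gene PRM1 (2.22 ± 0.09), the peptide transporter gene PTR2 (2.20 ± 0.05), the kinase gene RCK1 (1.94 ± 0.33), the proline oxidase gene PUT1 (1.89 ± 0.10), IFH1, a coactivator of ribosomal protein genes (1.75 ± 0.07), and GCV1, of the glycine cleavage system (1.69 ± 0.06). Among the 10 largest falls were also the subtelomeric COS12 (-2.56 ± 0.12), the flavohemoglobin gene YHB1 (-1.98 ± 0.05), the zinc-regulated alcohol dehydrogenase gene ADH4 (-1.69 ± 0.07), the ATPase inhibitor gene INH1 (-1.58 ± 0.07) and THP3 (-1.49 ± 0.05). MET6, SAM2 and MET3, which act in sulfate assimilation and the methionine cycle, fell too (-1.74 ± 0.05, -1.72 ± 0.05 and -1.63 ± 0.07). Among these rises the highest limma adjusted p was 4.30e-04, of RCK1, and among these falls it was 3.69e-08, of COS12. COS12 belongs to a family of near-identical subtelomeric genes, among which reads are hard to assign.

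By list, mating genes rose in sac3∆. Of the pheromone response genes 22 of 26 rose, 0 fell and 4 did not pass, and 22 rose and 0 fell adjusted over the list alone (limma camera adjusted p = 2.75e-10, adjusted p = 0.0138 with an estimated correlation). SST2, which desensitises cells to pheromone, was among them (1.26). Of the a-cell markers 7 of 7 rose, 0 fell and 0 did not pass, and 7 rose and 0 fell adjusted over the list alone (limma camera adjusted p = 7.33e-06, adjusted p = 0.168 with an estimated correlation). BAR1 stood at 1.13, STE2 at 0.99 and ASG7 at 1.40. Of the flocculin and adhesion genes 10 of 16 rose, 2 fell and 4 did not pass, and 10 rose and 2 fell adjusted over the list alone (limma camera adjusted p = 0.0257, adjusted p = 0.425 with an estimated correlation). FIG2 stood at 1.19. Of the iron regulon 21 of 30 rose, 2 fell and 7 did not pass, and 21 rose and 2 fell adjusted over the list alone (limma camera adjusted p = 4.56e-05, adjusted p = 0.189 with an estimated correlation). The siderophore transporter gene ARN1 stood at 0.87 and the copper transporter gene CCC2 at 0.80. Of the mitotic (G2/M and mitotic exit) genes 18 of 22 rose, 0 fell and 4 did not pass, and 18 rose and 0 fell adjusted over the list alone (limma camera adjusted p = 1.90e-06, adjusted p = 0.122 with an estimated correlation). The polo kinase gene CDC5 stood at 0.80 and the cyclin gene CLB2 at 0.53. Of the DNA damage response genes 8 of 18 rose, 0 fell and 10 did not pass, and 8 rose and 0 fell adjusted over the list alone (limma camera adjusted p = 0.0268, adjusted p = 0.181 with an estimated correlation). RNR3 stood at 0.59. Of the general stress genes 19 of 54 rose, 2 fell and 33 did not pass, and 18 rose and 2 fell adjusted over the list alone (limma camera adjusted p = 0.0288, adjusted p = 0.790 with an estimated correlation). TKL2 stood at 1.41 and DDR48 at 0.60.

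Ribosomal protein genes fell in sac3∆ with a median of -0.73. Of these 0 of 139 rose, 133 fell and 6 did not pass, and 0 rose and 136 fell adjusted over the list alone (limma camera adjusted p = 2.57e-36, adjusted p = 0.267 with an estimated correlation). RPL9A stood at -1.17, RPL35A at -0.83 and ASC1 at -0.92, while non-member genes of like abundance had a median of -0.12. Sulfate and methionine genes fell as a list: 5 of 34 rose, 18 fell and 11 did not pass, and 5 rose and 18 fell adjusted over the list alone (limma camera adjusted p = 4.42e-05, adjusted p = 0.0245 with an estimated correlation). The adenylylsulfate kinase gene MET14 stood at -1.18. Of the phospholipid synthesis genes 0 of 18 rose, 13 fell and 5 did not pass, and 0 rose and 13 fell adjusted over the list alone (limma camera adjusted p = 2.45e-05, adjusted p = 0.193 with an estimated correlation). The inositol synthase gene INO1 stood at -1.16, the fatty acid synthase genes FAS1 and FAS2 at -1.25 and -1.03, and ACC1 at -1.01. Of the ergosterol genes 1 of 25 rose, 17 fell and 7 did not pass, and 1 rose and 17 fell adjusted over the list alone (limma camera adjusted p = 6.12e-07, adjusted p = 0.195 with an estimated correlation). ERG13 stood at -0.56 and ERG20 at -0.72. Of the respiratory chain genes 3 of 35 rose, 25 fell and 7 did not pass, and 4 rose and 28 fell adjusted over the list alone (limma camera adjusted p = 2.81e-08, adjusted p = 0.178 with an estimated correlation). The cytochrome c gene CYC1 stood at -1.38 and ATP2 at -0.72, and matched genes had a median of -0.16 against -0.40.

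Glycolytic genes fell with a median of -0.52 in sac3∆, with abundance-matched genes at -0.14: 2 of 18 rose, 14 fell and 2 did not pass, and 2 rose and 15 fell adjusted over the list alone (limma camera adjusted p = 6.09e-05, adjusted p = 0.391 with an estimated correlation). ENO2 stood at -1.07 and HXK2 at -0.66. Of the heat shock and chaperone genes 2 of 30 rose, 19 fell and 9 did not pass, and 3 rose and 19 fell adjusted over the list alone (limma camera adjusted p = 5.18e-04, adjusted p = 0.488 with an estimated correlation). HSC82 stood at -0.96 and SSE1 at -0.84, and matched genes had a median of -0.25 against -0.29. Of the Gcn4-linked amino acid genes 8 of 52 rose, 26 fell and 18 did not pass, and 8 rose and 26 fell adjusted over the list alone (limma camera adjusted p = 4.74e-04, adjusted p = 0.519 with an estimated correlation). LYS9 stood at -0.89 and SER33 at -0.90. Of the purine and glycine cleavage genes 5 of 20 rose, 13 fell and 2 did not pass, and 5 rose and 13 fell adjusted over the list alone (limma camera adjusted p = 0.0389, adjusted p = 0.425 with an estimated correlation). GCV1 and GCV2 were up (1.69 and 1.41) and the IMP dehydrogenase genes IMD2 and IMD3 were down (-1.21 and -0.88). Of the TCA cycle genes 3 of 20 rose, 9 fell and 8 did not pass, and 3 rose and 9 fell adjusted over the list alone (limma camera adjusted p = 0.0446, adjusted p = 0.496 with an estimated correlation), a fall that turned to a rise after quantile normalization (adjusted p = 0.933). LPD1 stood at -0.67 and IDH1 at 0.75. After quantile normalization the limma camera calls of heat shock (adjusted p = 0.605), Gcn4-linked (adjusted p = 0.260), purine (adjusted p = 0.445), glycolysis (adjusted p = 0.0519) and flocculin genes (adjusted p = 0.0584) ended, and that of the purine list ended with medians set equal.

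Across all genes, 3156 of 6124 tested passed in sac3∆ (limma, adjusted p threshold 0.05), 1681 up and 1475 down, and 133 changed at least 2-fold. Over all 6124 features, the 3 mutant values lay beyond all 3 wild type values in 59.3%, which chance gives in 10%. The median size of the passing changes was 0.37 on the log2 scale. The division into rises and falls depends on scaling: 53.3% of passing genes rose as deposited, and 37.8% when the median of all genes was set equal in every sample.

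The comparison of R288D with wild type asks which transcripts depend on the Sac3 residue altered in this variant, where SAC3 itself is expressed. FIG1 rose most, to 20.7 ± 1.19 RPKM from 0.784 ± 0.101 (3.61 ± 0.10), and PRM1, AGA1 and AGA2 rose by 2.77 ± 0.09, 2.48 ± 0.11 and 2.14 ± 0.06. ZPS1 fell most, to 9.35 ± 2.70 RPKM (-5.52 ± 0.14), and ZRT1 fell to 189.9 ± 18.1 RPKM (-2.38 ± 0.07). PTR2, PUT1 and MFA1 rose by 2.17 ± 0.05, 2.04 ± 0.10 and 1.96 ± 0.21.

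The remaining large rises were in the small heat shock protein gene HSP26 (1.82 ± 0.15), the urea amidolyase gene DUR12 (1.75 ± 0.06) and MF(ALPHA)1, which encodes alpha-factor (1.76 ± 0.18, at 12.9 ± 2.96 RPKM against 3.07 ± 0.259). The remaining large falls were in COS12 (-2.21 ± 0.12), the cell wall mannoprotein gene CWP1 (-1.95 ± 0.15), MET3 (-1.76 ± 0.07), ADH4 (-1.67 ± 0.07), YHB1 (-1.59 ± 0.05), THP3 (-1.48 ± 0.05), INH1 (-1.39 ± 0.07) and the IMP dehydrogenase gene IMD2 (-1.39 ± 0.08). The highest limma adjusted p was 1.25e-05 among the 10 rises (MFA1) and 1.38e-06 among the 10 falls (CWP1).

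Mating genes rose in R288D as lists. For pheromone response 21 of 26 rose, 0 fell and 5 did not pass, and 21 rose and 0 fell adjusted over the list alone (limma camera adjusted p = 2.06e-11, adjusted p = 0.0138 with an estimated correlation). FUS1 stood at 1.70 and SST2 at 1.40. For a-cell markers 7 of 7 rose, 0 fell and 0 did not pass, and 7 rose and 0 fell adjusted over the list alone (limma camera adjusted p = 2.62e-06, adjusted p = 0.150 with an estimated correlation). BAR1 stood at 1.27 and STE2 at 1.14. For alpha-cell markers 3 of 4 rose, 0 fell and 1 did not pass, and 3 rose and 0 fell adjusted over the list alone (limma camera adjusted p = 0.0331, adjusted p = 0.195 with an estimated correlation). The alpha-agglutinin gene SAG1 stood at 1.70. For flocculin and adhesion genes 9 of 16 rose, 1 fell and 6 did not pass, and 9 rose and 2 fell adjusted over the list alone (limma camera adjusted p = 0.0270, adjusted p = 0.425 with an estimated correlation). FIG2 stood at 1.21 and FLO8 at 0.58. For the iron regulon 15 of 30 rose, 4 fell and 11 did not pass, and 15 rose and 4 fell adjusted over the list alone (limma camera adjusted p = 0.0197, adjusted p = 0.391 with an estimated correlation). ARN1 stood at 0.76 and ISU2 at 0.97. For mitotic genes 16 of 22 rose, 1 fell and 5 did not pass, and 16 rose and 1 fell adjusted over the list alone (limma camera adjusted p = 6.09e-05, adjusted p = 0.177 with an estimated correlation). CDC5 stood at 0.92 and CLB2 at 0.72. For DNA damage response 12 of 18 rose, 1 fell and 5 did not pass, and 12 rose and 1 fell adjusted over the list alone (limma camera adjusted p = 0.00205, adjusted p = 0.0872 with an estimated correlation). RNR3 stood at 0.96 and HUG1 at 1.45.

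Ribosomal protein genes fell in R288D with a median of -0.71, with abundance-matched genes at -0.18: 0 of 139 rose, 135 fell and 4 did not pass, and 1 rose and 136 fell adjusted over the list alone (limma camera adjusted p = 2.57e-36, adjusted p = 0.267 with an estimated correlation). RPL9A stood at -1.11 and RPL35A at -0.77. For sulfate and methionine genes 4 of 34 rose, 18 fell and 12 did not pass, and 5 rose and 18 fell adjusted over the list alone (limma camera adjusted p = 6.93e-05, adjusted p = 0.0245 with an estimated correlation). MET14 stood at -1.26 and the sulfite reductase gene MET5 at -1.01. For ergosterol genes 1 of 25 rose, 17 fell and 7 did not pass, and 1 rose and 19 fell adjusted over the list alone (limma camera adjusted p = 2.62e-06, adjusted p = 0.215 with an estimated correlation). ERG6 stood at -1.07. For the respiratory chain 1 of 35 rose, 27 fell and 7 did not pass, and 1 rose and 27 fell adjusted over the list alone (limma camera adjusted p = 1.06e-08, adjusted p = 0.177 with an estimated correlation). CYC1 stood at -1.21 and COX4 at -0.91, and matched genes had a median of -0.20 against -0.40. For glycolysis 3 of 18 rose, 13 fell and 2 did not pass, and 3 rose and 14 fell adjusted over the list alone (limma camera adjusted p = 0.00292, adjusted p = 0.496 with an estimated correlation). ENO2 stood at -0.85 and HXK2 at -0.62 but TDH1 at 0.68, and the matched median was -0.33 against -0.40. For phospholipid synthesis 8 of 18 rose, 4 fell and 6 did not pass, and 9 rose and 4 fell adjusted over the list alone (limma camera adjusted p = 0.459, adjusted p = 0.796 with an estimated correlation). INO1 rose by 1.58 ± 0.08 and FAS1 and ACC1 fell (-0.88 and -0.73). After quantile normalization the list was called up (adjusted p = 0.0326), a call lost at adjusted p = 0.378 with an estimated correlation.

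The remaining called lists in R288D were as follows. For heat shock and chaperone genes 2 of 30 rose, 16 fell and 12 did not pass, and 2 rose and 16 fell adjusted over the list alone (limma camera adjusted p = 0.00983, adjusted p = 0.614 with an estimated correlation), a fall that turned to a rise after quantile normalization (adjusted p = 0.733). HSC82 stood at -0.75 but the HSP70 gene SSA3 at 1.16. For Gcn4-linked amino acid genes 11 of 52 rose, 25 fell and 16 did not pass, and 11 rose and 25 fell adjusted over the list alone (limma camera adjusted p = 0.0358, adjusted p = 0.763 with an estimated correlation). LYS9 stood at -0.82 and HOM6 at -0.72. For purine and glycine cleavage genes 5 of 20 rose, 13 fell and 2 did not pass, and 5 rose and 13 fell adjusted over the list alone (limma camera adjusted p = 0.0472, adjusted p = 0.425 with an estimated correlation). GCV1 stood at 1.75 and IMD3 at -0.85. For the TCA cycle 4 of 20 rose, 10 fell and 6 did not pass, and 4 rose and 12 fell adjusted over the list alone (limma camera adjusted p = 0.0213, adjusted p = 0.425 with an estimated correlation). LPD1 stood at -0.58 and IDH1 at 0.50. For small nuclear and nucleolar RNAs 3 of 84 rose, 12 fell and 69 did not pass, and 3 rose and 2 fell adjusted over the list alone (limma camera adjusted p = 0.0268, adjusted p = 0.790 with an estimated correlation). SNR68 stood at -2.06 but SNR19 at 0.62. After quantile normalization the limma camera calls of Gcn4-linked (adjusted p = 0.973), purine (adjusted p = 0.469), glycolysis (adjusted p = 0.859), TCA (adjusted p = 0.909), flocculin (adjusted p = 0.0789) and small RNA genes (adjusted p = 0.914) ended, and those of the purine and small RNA lists ended with medians set equal. Of general stress genes 15 of 54 rose, 5 fell and 34 did not pass, and 15 rose and 4 fell adjusted over the list alone (limma camera adjusted p = 0.297). They were called up after quantile normalization (adjusted p = 6.92e-05 by limma camera at the preset correlation), a call that was lost there at adjusted p = 0.738 with an estimated correlation. The list medians of the 3 R288D samples ran from -0.18 to 0.29, so as deposited the list did not rise in each of them.

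Across all genes, 3108 passed in R288D (limma, adjusted p threshold 0.05), 1611 up and 1497 down, and 128 changed at least 2-fold. The 3 mutant values lay beyond all wild type values in 54.9% of all 6124 features, where chance gives 10%. The share that rose was 51.8% as deposited and 38.8% with medians set equal. The label of the R288D plasmid names no 13MYC tag, so tag and substitution are not separated in this comparison.

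The comparison of cdk8∆ with wild type asks which transcripts depend on the Mediator kinase. ADH2 (YMR303C, chromosome XIII, 873291 to 874337, minus strand), the glucose-repressed alcohol dehydrogenase gene, rose most, to 127 ± 7.33 RPKM from 8.27 ± 5.31 (3.93 ± 0.41). YGP1 (YNL160W, chromosome XIV, 336545 to 337609, plus strand), which encodes a secreted stress glycoprotein, fell most, to 48.6 ± 2.42 RPKM from 819 ± 68.9 (-4.04 ± 0.06), and the stress gene HSP12 fell to 142 ± 19.0 from 1819 ± 109.6 RPKM (-3.68 ± 0.11). PTR2 (YKR093W, chromosome XI, 615730 to 617535, plus strand) rose by 3.52 ± 0.05, the peroxisomal acyl-CoA oxidase gene POX1 by 3.19 ± 0.12 and the mitochondrial citrate synthase gene CIT3 by 3.02 ± 0.20.

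The other large rises in cdk8∆ were DPA10 (3.81 ± 0.19), FRM2 (3.51 ± 0.17), SRL4 (2.92 ± 0.16) and the meiosis and sporulation genes SPO20 (2.99 ± 0.17), CSM4 (2.96 ± 0.26) and SPS1 (2.90 ± 0.12). The other large falls were the polyamine transporter gene TPO2 (-3.37 ± 0.11), YRO2 (-3.33 ± 0.07), CIP1 (-3.00 ± 0.14), FMP48 (-2.95 ± 0.16), the membrane heat shock gene HSP30 (-2.87 ± 0.08), PNS1 (-2.55 ± 0.16), BSC1 (-2.52 ± 0.13) and RCK1 (-2.52 ± 0.33). The highest limma adjusted p was 5.87e-06 among the 10 rises (ADH2) and 3.92e-05 among the 10 falls (RCK1).

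Among lists that rose in cdk8∆, nicotinate and thiamine genes were called with either correlation: 22 of 25 rose, 1 fell and 2 did not pass, and 22 rose and 1 fell adjusted over the list alone (limma camera adjusted p = 1.09e-06, adjusted p = 0.0138 with an estimated correlation). The thiamine transporter gene THI7 stood at 1.82 and BNA2 at 1.66. Sulfate and methionine genes rose, opposite to the TREX-2 mutants: 24 of 34 rose, 7 fell and 3 did not pass, and 24 rose and 7 fell adjusted over the list alone (limma camera adjusted p = 0.00176, adjusted p = 0.0619 with an estimated correlation). MET1 stood at 1.13 but MET6 at -1.22 and SAM1 at -1.08. Of pheromone response genes 19 of 26 rose, 0 fell and 7 did not pass, and 20 rose and 1 fell adjusted over the list alone (limma camera adjusted p = 9.54e-07, adjusted p = 0.0261 with an estimated correlation). FUS1 and FUS2 stood at 2.10 and 2.37. Of alpha-cell markers 4 of 4 rose, 0 fell and 0 did not pass, and 4 rose and 0 fell adjusted over the list alone (limma camera adjusted p = 0.0358, adjusted p = 0.204 with an estimated correlation). STE3 stood at 0.95. Of a-cell markers 3 of 7 rose, 2 fell and 2 did not pass, and 3 rose and 2 fell adjusted over the list alone (limma camera adjusted p = 0.373, adjusted p = 0.781 with an estimated correlation). ASG7 stood at 2.54 and STE2 at -0.35. That list was not called as deposited, and was called up after quantile normalization (limma camera adjusted p = 0.0477), a call lost there at adjusted p = 0.378 with an estimated correlation. Of glucose-repressed genes 18 of 28 rose, 5 fell and 5 did not pass, and 18 rose and 5 fell adjusted over the list alone (limma camera adjusted p = 0.0101, adjusted p = 0.763 with an estimated correlation). MLS1 stood at 1.94 but MDH2 at -1.45. Of galactose genes 5 of 8 rose, 1 fell and 2 did not pass, and 5 rose and 1 fell adjusted over the list alone (limma camera adjusted p = 0.0384, adjusted p = 0.380 with an estimated correlation). GAL2 stood at 1.71 and GAL7 at 1.68. Of early meiosis genes 17 of 27 rose, 1 fell and 9 did not pass, and 17 rose and 1 fell adjusted over the list alone (limma camera adjusted p = 2.30e-04, adjusted p = 0.0872 with an estimated correlation). The list also holds genes of later sporulation, among them SPR3 and SPS19, which stood at 2.35 and 1.93. The list median was 0.66, against 0.34 for abundance-matched genes. Of the iron regulon 19 of 30 rose, 6 fell and 5 did not pass, and 19 rose and 6 fell adjusted over the list alone (limma camera adjusted p = 0.0223, adjusted p = 0.391 with an estimated correlation). FRE4 stood at 2.36 but FET3 at -0.98. Of purine and glycine cleavage genes 11 of 20 rose, 3 fell and 6 did not pass, and 11 rose and 3 fell adjusted over the list alone (limma camera adjusted p = 0.0200, adjusted p = 0.380 with an estimated correlation). IMD2 stood at 2.10.

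General stress genes fell in cdk8∆ with a median of -0.96, with matched genes at -0.27: 3 of 54 rose, 41 fell and 10 did not pass, and 4 rose and 42 fell adjusted over the list alone (limma camera adjusted p = 1.55e-09, adjusted p = 0.425 with an estimated correlation). HOR7 stood at -1.74 and SPI1 at -2.04. Of heat shock and chaperone genes 0 of 30 rose, 26 fell and 4 did not pass, and 0 rose and 27 fell adjusted over the list alone (limma camera adjusted p = 9.46e-10, adjusted p = 0.251 with an estimated correlation). SSA4 stood at -1.58 and BTN2 at -2.10, and matched genes had a median of -0.35 against -0.60. Of ribosome biogenesis genes 1 of 111 rose, 99 fell and 11 did not pass, and 1 rose and 104 fell adjusted over the list alone (limma camera adjusted p = 2.59e-13, adjusted p = 0.489 with an estimated correlation). BRX1 stood at -0.94 and RPA34 at -0.80, and matched genes had a median of -0.01 against -0.48. Ribosomal protein genes fell with a median of -0.64, with matched genes at -0.47: 0 of 139 rose, 137 fell and 2 did not pass, and 0 rose and 137 fell adjusted over the list alone (limma camera adjusted p = 6.94e-24, adjusted p = 0.380 with an estimated correlation). RPS9A stood at -1.21. Of glycolytic genes 2 of 18 rose, 16 fell and 0 did not pass, and 2 rose and 16 fell adjusted over the list alone (limma camera adjusted p = 4.20e-07, adjusted p = 0.280 with an estimated correlation). PGK1 stood at -1.46 and the pyruvate kinase gene CDC19 at -1.46. The list median was -1.16, against -0.51 for matched genes. Of the respiratory chain 2 of 35 rose, 26 fell and 7 did not pass, and 2 rose and 27 fell adjusted over the list alone (limma camera adjusted p = 3.98e-06, adjusted p = 0.222 with an estimated correlation). ATP5 stood at -0.66, and matched genes had a median of -0.24 against -0.48. Of ergosterol genes 4 of 25 rose, 12 fell and 9 did not pass, and 4 rose and 13 fell adjusted over the list alone (limma camera adjusted p = 0.0342, adjusted p = 0.519 with an estimated correlation), a fall that turned to a rise after quantile normalization (adjusted p = 0.899). ERG25 stood at -1.35. Of phospholipid genes 2 of 18 rose, 10 fell and 6 did not pass, and 2 rose and 10 fell adjusted over the list alone (limma camera adjusted p = 0.0431, adjusted p = 0.482 with an estimated correlation). INO1 stood at -2.04 ± 0.08.

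Cell wall and cell cycle lists fell too in cdk8∆. Of the Rlm1-linked cell wall integrity genes 3 of 24 rose, 17 fell and 4 did not pass, and 3 rose and 18 fell adjusted over the list alone (limma camera adjusted p = 3.22e-05, adjusted p = 0.259 with an estimated correlation). PST1 stood at -2.25, GAS1 at -1.53 and, upward, the glucan synthase gene GSC2 at 1.82. Of mitotic genes 1 of 22 rose, 17 fell and 4 did not pass, and 1 rose and 17 fell adjusted over the list alone (limma camera adjusted p = 1.16e-05, adjusted p = 0.150 with an estimated correlation). The daughter separation genes EGT2 and DSE2 stood at -1.84 and -1.64. Of cyclin, S phase and histone genes 2 of 23 rose, 16 fell and 5 did not pass, and 2 rose and 16 fell adjusted over the list alone (limma camera adjusted p = 9.46e-05, adjusted p = 0.215 with an estimated correlation). The histone genes HHF2 and HHT2 stood at -1.15 and -1.09. Of multidrug resistance genes 3 of 17 rose, 10 fell and 4 did not pass, and 4 rose and 10 fell adjusted over the list alone (limma camera adjusted p = 0.0358, adjusted p = 0.222 with an estimated correlation), a call that ended with medians set equal. The drug pump gene PDR5 stood at -1.54 and GRE2 at -2.40. After quantile normalization the limma camera calls of ribosomal protein (adjusted p = 0.997), respiratory (adjusted p = 0.318), phospholipid (adjusted p = 0.973), early meiosis (adjusted p = 0.163), galactose (adjusted p = 0.0787), iron (adjusted p = 0.0535) and alpha-cell genes (adjusted p = 0.116) ended.

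Across all genes, 3802 passed in cdk8∆ (limma, adjusted p threshold 0.05), 1926 up and 1876 down, and 487 changed at least 2-fold. The 3 mutant values lay beyond all wild type values in 72.9% of all 6124 features, where chance gives 10%. The share that rose was 50.7% as deposited and 42.9% with medians set equal. This group differs from wild type also in having native in place of tagged plasmid SAC3, so the kinase deletion and the source of SAC3 are not separated.

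Several lists were called in no mutant or only in cdk8∆, and their other results were as follows, by limma camera. For ribosome biogenesis 24 of 111 rose, 22 fell and 65 did not pass in sac3∆ and 19 rose and 19 fell in R288D (20 and 20, and 17 and 16, adjusted over the list alone, limma camera adjusted p = 0.751 and 0.987). NOP56 stood at -0.42 and SPB1 at 0.72 in sac3∆. Hexose transporter counts (13 genes) were 5 rose and 0 fell in sac3∆, 5 and 1 in R288D, and 5 and 7 in cdk8∆ (adjusted over the list alone, 5 and 0, 5 and 1, and 5 and 7, adjusted p = 0.164, 0.550 and 0.677). HXT3 stood at -1.26 in cdk8∆. Phosphate regulon counts (20 genes) were 5 rose and 9 fell in sac3∆, 6 and 7 in R288D, and 13 and 2 in cdk8∆ (adjusted over the list alone, 5 and 9, 7 and 7, and 13 and 5, adjusted p = 0.477, 0.920 and 0.0717). PHO89 stood at 1.94 and PHM8 at -2.37 in cdk8∆. Oxidative stress counts (22 genes) were 5 rose and 9 fell in sac3∆, 6 and 11 in R288D, and 12 and 8 in cdk8∆ (adjusted over the list alone, 5 and 10, 7 and 11, and 12 and 8, adjusted p = 0.291, 0.464 and 0.537). AHP1 stood at -1.94 and CTA1 at 2.48 in cdk8∆, and the list was called up there after quantile normalization (adjusted p = 0.0264), a call lost at adjusted p = 0.370 with an estimated correlation. Counts for aerobic repression and seripauperin genes (17 genes) were 5 rose and 6 fell in sac3∆, 3 and 5 in R288D, and 8 and 3 in cdk8∆ (adjusted over the list alone, 6 and 6, 3 and 5, and 8 and 3, adjusted p = 0.763, 0.678 and 0.0627). ANB1 stood at 2.55 in cdk8∆. Counts for the auxotrophic markers (6 genes) were 1 rose and 2 fell in sac3∆, 1 and 2 in R288D, and 2 and 0 in cdk8∆ (adjusted over the list alone, 1 and 2, 1 and 2, and 2 and 0, adjusted p = 0.791, 0.752 and 0.356). LEU2 stood at 0.51 in cdk8∆.

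In the TREX-2 mutants, galactose genes gave 2 up and 1 down of 8 in sac3∆ and 2 up and 0 down in R288D (2 and 1, and 2 and 0, adjusted over the list alone, limma camera adjusted p = 0.646 and 0.646). GAL4 stood at 0.52 and 0.40. Glucose-repressed genes gave 10 up and 1 down of 28, and 9 up and 4 down (10 and 1, and 9 and 4, adjusted over the list alone, limma camera adjusted p = 0.0883 and 0.477). POX1 stood at -0.70 and -0.73. Early meiosis genes gave 8 up and 1 down of 27, and 10 up and 1 down (6 and 1, and 9 and 1, adjusted over the list alone, limma camera adjusted p = 0.0818 and 0.144). RED1 stood at 0.92 and 0.91. Nicotinate and thiamine genes gave 4 up and 8 down of 25, and 6 up and 5 down (4 and 8, and 6 and 5, adjusted over the list alone, limma camera adjusted p = 0.238 and 0.677). Cell wall integrity genes gave 7 up and 5 down of 24, and 6 up and 7 down (8 and 7, and 6 and 7, adjusted over the list alone, limma camera adjusted p = 0.915 and 0.677). GSC2 stood at 1.27 and 1.46.

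Cyclin, S phase and histone genes gave 7 up and 9 down of 23 in sac3∆, and 9 up and 12 down in R288D (8 and 9, and 9 and 12, adjusted over the list alone, limma camera adjusted p = 0.477 and 0.550). The histone gene HTA2 stood at -0.53 and -0.70. Multidrug resistance genes gave 7 up and 2 down of 17, and 7 up and 1 down (7 and 2, and 7 and 1, adjusted over the list alone, limma camera adjusted p = 0.225 and 0.110). PDR12 stood at 0.74 and 0.85. In sac3∆, of the alpha-cell markers 3 of 4 rose, 0 fell and 1 did not pass (3 rose and 0 fell adjusted over the list alone, limma camera adjusted p = 0.0865), and of the small nuclear and nucleolar RNAs 4 of 84 rose, 5 fell and 75 did not pass (3 rose and 3 fell adjusted over the list alone, limma camera adjusted p = 0.373). In cdk8∆, of the small RNAs 3 of 84 rose, 15 fell and 66 did not pass, and 1 rose and 4 fell adjusted over the list alone (limma camera adjusted p = 0.319). After quantile normalization the list was called up (limma camera adjusted p = 0.0359), a call lost at adjusted p = 0.801 with an estimated correlation, and the fall of the U2 RNA gene LSR1 (-0.65) turned to a rise under that scaling. In cdk8∆ also, of the flocculin genes 6 of 16 rose, 0 fell and 10 did not pass, and 6 rose and 0 fell adjusted over the list alone (limma camera adjusted p = 0.200). Of the Gcn4-linked genes there 14 of 52 rose, 21 fell and 17 did not pass, and 15 rose and 21 fell adjusted over the list alone (limma camera adjusted p = 0.200). ARG3 stood at -2.14. Of the TCA genes there 3 of 20 rose, 9 fell and 8 did not pass, and 3 rose and 9 fell adjusted over the list alone (limma camera adjusted p = 0.0712). Of the DNA damage genes there 5 of 18 rose, 7 fell and 6 did not pass, and 5 rose and 7 fell adjusted over the list alone (limma camera adjusted p = 0.678). RNR1 stood at -1.07. No Ty element was in the table, and the mitochondrially encoded genes (31 in the table) held 0 tested members. The signs of median, mean and camera direction against wild type differed only among lists not called: in sac3∆ for TREX-2, phosphate, ribosome biogenesis, cyclin and S phase, and seripauperin genes, in R288D for export, galactose, hexose, phosphate, cyclin and S phase, and seripauperin genes, and in cdk8∆ for TREX-2, kinase, other Mediator, SAGA and DNA damage genes.

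As lists, the complexes under study and their partners were not called in any mutant. Of 5 TREX-2 subunits (SAC3 included), 2 rose and 2 fell in sac3∆, 3 and 1 in R288D, and 1 and 2 in cdk8∆ (adjusted over the list alone, 2 and 2, 3 and 1, and 1 and 2), with limma camera adjusted p = 0.599, 0.445 and 0.593. Of 4 Mediator kinase subunits (SSN3 included), 1 rose and 0 fell in sac3∆, 3 and 0 in R288D, and 3 and 1 in cdk8∆ (adjusted over the list alone, 1 and 0, 3 and 1, and 3 and 1), with limma camera adjusted p = 0.595, 0.369 and 0.740. The kinase median in cdk8∆ was 0.27 but its mean was -1.10, because the mean includes the deleted SSN3. Among 21 other Mediator subunits, 7 rose and 3 fell in sac3∆, 4 and 5 in R288D, and 6 and 4 in cdk8∆ (adjusted over the list alone, 7 and 3, 4 and 5, and 6 and 4), with limma camera adjusted p = 0.677, 0.802 and 0.646, and the values of GAL11 were 0.38 in sac3∆ and 0.30 in R288D. Of 20 THO, TREX and mRNA export factors, 7 rose and 5 fell in sac3∆, 5 and 5 in R288D, and 3 and 11 in cdk8∆ (adjusted over the list alone, 7 and 5, 5 and 5, and 3 and 11), with limma camera adjusted p = 0.884, 0.987 and 0.0712. YRA1, an mRNA export adaptor, rose by 0.92 and 0.87 in sac3∆ and R288D and fell to -0.81 in cdk8∆, while the export helicase gene DBP5 changed by -0.74, -0.70 and -0.49. Of 18 SAGA subunits, 8 rose and 1 fell in sac3∆, 6 and 1 in R288D, and 5 and 7 in cdk8∆ (adjusted over the list alone, 8 and 1, 6 and 1, and 5 and 7), with limma camera adjusted p = 0.164, 0.291 and 0.763, and SPT3 rose by 0.54 and 0.44 in the TREX-2 mutants.

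**Figure D2:**
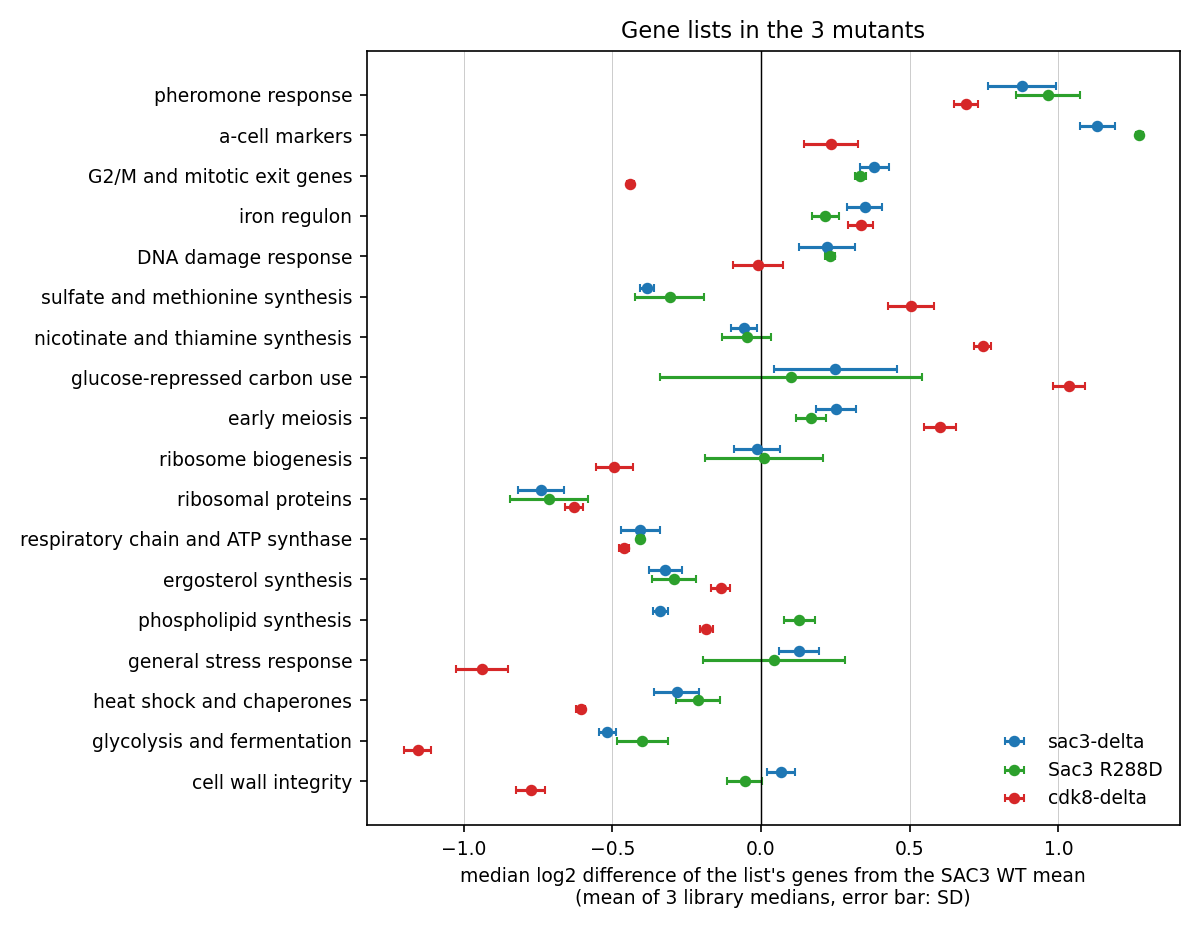
Mean over the 3 samples of each mutant of the list's median log2 change from the wild type mean, with bars for the SD (n = 3), for 18 gene lists in sac3∆, R288D and cdk8∆. Pheromone response genes lie at 0.88, 0.96 and 0.69 and ribosomal protein genes at -0.74, -0.71 and -0.63. Genes matched to the ribosomal protein genes in abundance, which are not plotted, had fitted medians of -0.12, -0.18 and -0.47.

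The comparison of R288D with sac3∆ asks where the substitution and the loss of the whole protein part ways. INO1 (YJL153C, chromosome X, 134332 to 135933, minus strand), which encodes inositol-3-phosphate synthase, lay at 292 ± 24.3 RPKM in R288D and 42.9 ± 3.87 in sac3∆, with wild type between them at 97.2 ± 3.80 (direct difference 2.74 ± 0.08, limma adjusted p = 1.86e-09). ZRT1 was higher in R288D by 1.96 ± 0.07, and MF(ALPHA)1, SAM2 and the reductase gene FRE7 by 1.13 ± 0.18, 0.90 ± 0.05 and 0.88 ± 0.08. Lower in R288D were the reductase gene FRE5 (-0.84 ± 0.17), the siderophore-binding mannoprotein genes FIT2 and FIT3 (-0.83 ± 0.07 and -0.52 ± 0.11), the subtelomeric COS8 (-0.72 ± 0.06) and the glucose transporter gene HXT1 (-0.49 ± 0.09). The calls of FRE5, FIT3 and HXT1 ended under at least 2 alternatives, and that of MF(ALPHA)1 ended when only these groups were fitted.

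Phospholipid synthesis genes were higher in R288D than in sac3∆: of 18, 14 were higher, 0 lower and 4 did not pass, and 16 were higher adjusted over the list alone (limma camera adjusted p = 1.71e-33, adjusted p = 0.00526 with an estimated correlation). Beside INO1 these included the inositol transporter gene ITR1 (0.77 ± 0.05), OPI3 (0.72 ± 0.06), PSD1 (0.62 ± 0.05), CHO1 (0.55 ± 0.06) and the activator gene INO2 (0.53 ± 0.06), members chosen after their values were seen. PIS1 (-0.03), INO4 (0.19), EKI1 (0.22) and CKI1 (0.34) did not pass. In the iron regulon 1 of 30 genes was higher and 7 were lower, with 2 and 10 adjusted over the list alone (limma camera adjusted p = 1.56e-05, adjusted p = 0.208 with an estimated correlation). Tests of lists between mutants were adjusted over 111 results of their own. Between R288D and sac3∆ 13 of 37 lists were called by limma camera, and 1, phospholipid synthesis, held with an estimated correlation.

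Apart from phospholipid synthesis and iron, the called lists held 0 to 2 genes each that passed singly. By limma camera, called toward higher in R288D were glycolysis (2 higher and 0 lower of 18, adjusted p = 2.21e-06, adjusted p = 0.382 with an estimated correlation), Gcn4-linked genes (0 higher and 0 lower of 52, adjusted p = 1.73e-05, adjusted p = 0.494 with an estimated correlation) and heat shock genes (1 higher and 0 lower of 30, adjusted p = 1.50e-04, adjusted p = 0.494 with an estimated correlation). Also called that way by limma camera were pheromone response (1 higher and 0 lower of 26, adjusted p = 0.00889, adjusted p = 0.210 with an estimated correlation), nicotinate and thiamine synthesis (0 higher and 0 lower of 25, adjusted p = 0.0249, adjusted p = 0.183 with an estimated correlation), DNA damage response (1 higher and 0 lower of 18, adjusted p = 0.0316, adjusted p = 0.210 with an estimated correlation) and alpha-cell markers (1 higher and 0 lower of 4, adjusted p = 0.0363, adjusted p = 0.250 with an estimated correlation). Called toward lower by limma camera were small nuclear and nucleolar RNAs (0 higher and 0 lower of 84, adjusted p = 8.69e-04, adjusted p = 0.696 with an estimated correlation), general stress genes (1 higher and 0 lower of 54, adjusted p = 0.00745, adjusted p = 0.741 with an estimated correlation), glucose-repressed genes (0 higher and 0 lower of 28, adjusted p = 0.00762, adjusted p = 0.726 with an estimated correlation) and hexose transporters (0 higher and 1 lower of 13, adjusted p = 0.0335, adjusted p = 0.516 with an estimated correlation). Sample medians of the groups overlapped in each of these lists except alpha-cell markers. For glucose-repressed genes they ran from -0.25 to 0.60 in R288D and from 0.10 to 0.49 in sac3∆, and for general stress genes from -0.18 to 0.29 and from 0.05 to 0.18.

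In all, 84 genes differed between R288D and sac3∆ (limma, adjusted p threshold 0.05), SAC3 included, 64 higher and 20 lower in R288D, and 6 differed at least 2-fold. The values of the groups did not overlap in 12.0% of all 6124 features, where chance gives 10%. The count of 84 moved with the setting: without sac3∆ replicate 1 it was 53, without R288D replicate 2 it was 468, with only these groups fitted it was 17, and with array weights it was 829. The balance of directions moved as well: 230 were higher and 238 lower in R288D without its replicate 2, and 392 higher and 437 lower with array weights.

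The comparison of changes between mutants asks how far the TREX-2 mutants and the Mediator kinase mutant affect the same transcripts, as the study's title links these complexes. Genes that rose in all 3 mutants by the most included FIG1, PRM1, PTR2, FUS1 and FUS2, and genes that fell in all 3 by the most included ZRT1, YHB1, CWP1, INH1 and MET6. PTR2 rose by 2.20, 2.17 and 3.52 in sac3∆, R288D and cdk8∆, and FUS2 by 1.68, 1.70 and 2.37. YHB1 changed by -1.98, -1.59 and -1.58, and INH1 by -1.58, -1.39 and -1.51. In all, 583 genes rose in all 3 mutants and 718 fell, against 139 and 110 if the calls were independent (limma, adjusted p threshold 0.05). The comparisons share wild type samples, and sac3∆ and R288D share 1386 rises and 1275 falls, so this excess does not show sharing with cdk8∆. In 100 simulations with no effect a mean of 0 genes did so in all 3, and no pair shared more than 1 call, which speaks only to false calls. After quantile normalization, added after the data were seen, 334 rose and 335 fell in all 3.

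Between sac3∆ and R288D, 2661 genes passed in the same direction, 1386 up and 1275 down, against 442 and 361 if independent. These were 84.3% of the genes called in sac3∆. The 12 genes called in opposite directions were INO1, ITR1, OPI3, PSD1, FIT2, COS8, ENB1, EHT1, HEM25, HUA2, KSS1 and SAC3, of which INO1 stood at -1.16 and 1.58, and ITR1 at -0.28 and 0.49. Across genes, which are not independent replicates, Pearson's r was 0.896 and Spearman's rho 0.908. Shared wild type samples alone gave a mean r of 0.497 in 100 simulations with no effect, which cannot gauge real changes. The covariance was 0.151, against 0.00809 in those simulations, which gave a mean of 0.01 shared calls.

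Some genes moved oppositely in cdk8∆ and the TREX-2 mutants. RCK1 stood at 1.94, 1.66 and -2.52 in sac3∆, R288D and cdk8∆, IMD2 at -1.21, -1.39 and 2.10, and AMN1 at 0.75, 0.66 and -1.16. Between cdk8∆ and R288D, 1469 genes passed in the same direction, 675 up and 794 down, against 507 and 459 if independent, and 636 in opposite directions, against 964 if independent. Between sac3∆ and cdk8∆ these counts were 1502, 710 up and 792 down, against 529 and 452, and 609 in opposite directions, against 979. Pearson's r across genes was 0.239 and 0.260, with covariances of 0.0582 and 0.0654. Simulations with no effect gave r of 0.502 and 0.501, which cannot gauge real changes, and covariances of 0.00816 and 0.00813. After quantile normalization the shared counts with cdk8∆ fell to 787 (R288D) and 848 (sac3∆), and r to 0.0424 and 0.0646.

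**Figure D3:**
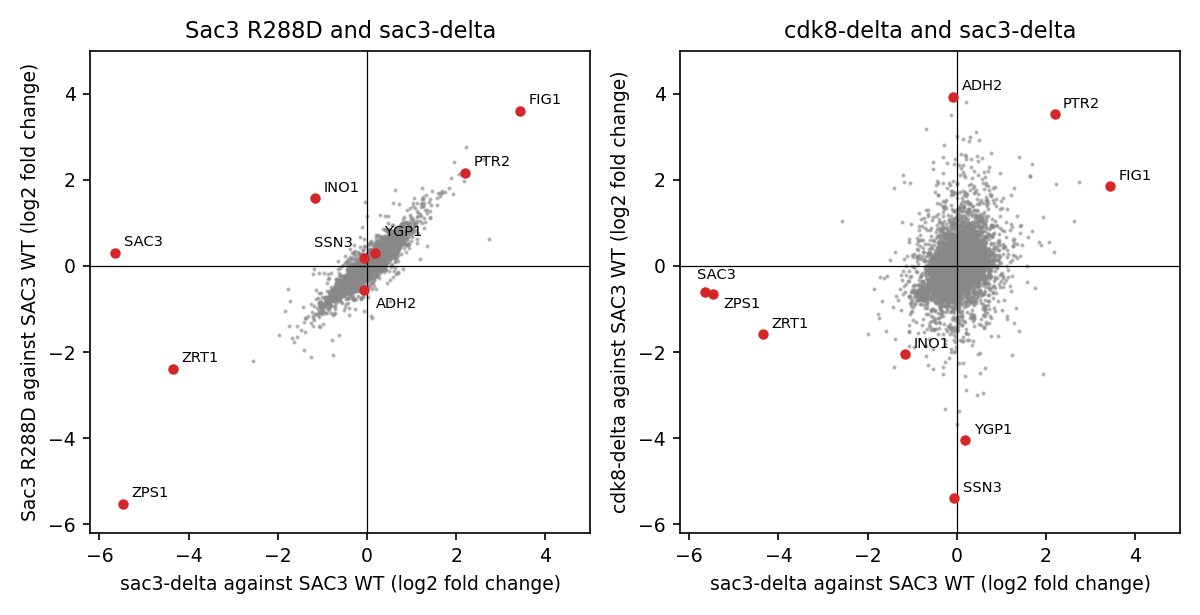
Log2 change from wild type in sac3∆ (horizontal axes) against that in R288D (first panel) and in cdk8∆ (second panel), a point per tested gene, with 9 genes marked in red. Pearson's r across genes is 0.896 in the first panel and 0.260 in the second.

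The direct comparisons with cdk8∆ ask where the TREX-2 mutants and the kinase mutant differ. YGP1, RCK1, HSP12 and HSP26 were higher in R288D than in cdk8∆ by 4.35 ± 0.06, 4.18 ± 0.33, 3.89 ± 0.11 and 3.89 ± 0.15, and INO1 by 3.62 ± 0.08. ZPS1, ADH2, POX1, FRM2 and CIT3 were lower, with differences of -4.88 ± 0.14, -4.48 ± 0.41, -3.92 ± 0.12, -3.66 ± 0.17 and -3.53 ± 0.20. In sac3∆ against cdk8∆ the largest positive differences were RCK1 (4.45 ± 0.33), YGP1 (4.23 ± 0.06), HSP12 (3.68 ± 0.11), FMP48 (3.54 ± 0.16) and CIP1 (3.46 ± 0.14). The largest negative ones were ZPS1 (-4.83 ± 0.14), ADH2 (-4.01 ± 0.41), POX1 (-3.89 ± 0.12), FRM2 (-3.65 ± 0.17) and COS12 (-3.62 ± 0.12). The highest limma adjusted p among these differences was 4.26e-06, of ADH2 in sac3∆ against cdk8∆.

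Relative to cdk8∆, of 54 general stress genes 44 were higher and 3 lower in R288D, and 45 and 2 in sac3∆ (44 and 3, and 45 and 2, adjusted over the list alone, with limma camera adjusted p = 1.51e-10 and 1.31e-11, and adjusted p = 0.424 and 0.420 with an estimated correlation). Of 111 ribosome biogenesis genes 93 were higher and 0 lower in R288D, and 91 and 0 in sac3∆ (93 and 0, and 92 and 1, adjusted over the list alone, with limma camera adjusted p = 1.18e-10 and 2.69e-10, and adjusted p = 0.569 and 0.569 with an estimated correlation). Of 22 mitotic genes 22 were higher and 0 lower in R288D, and 22 and 0 in sac3∆ (22 and 0, and 22 and 0, adjusted over the list alone, with limma camera adjusted p = 5.56e-10 and 3.04e-10, and adjusted p = 0.0452 and 0.0452 with an estimated correlation). Of 34 sulfate and methionine genes 3 were higher and 27 lower in R288D, and 2 and 25 in sac3∆ (3 and 27, and 2 and 27, adjusted over the list alone, with limma camera adjusted p = 5.52e-08 and 1.33e-08, and adjusted p = 0.00526 and 0.00526 with an estimated correlation). Of 25 nicotinate and thiamine genes 1 was higher and 21 lower in R288D, and 1 and 22 in sac3∆ (1 and 21, and 1 and 22, adjusted over the list alone, with limma camera adjusted p = 2.21e-06 and 4.61e-07, and adjusted p = 0.00942 and 0.00792 with an estimated correlation). Ribosomal protein genes were not called between these mutants (adjusted p = 0.135 and 0.0534 by limma camera). Relative to cdk8∆, 18 of 37 lists were called in R288D and 15 in sac3∆, and 3 held in each with an estimated correlation. In all, 3903 genes differed between R288D and cdk8∆ (limma, 1978 higher and 1925 lower in R288D, 563 at least 2-fold) and 3924 between sac3∆ and cdk8∆ (2015 and 1909, 556 at least 2-fold). The groups did not overlap in 69.2% and 72.4% of all 6124 features, where chance gives 10%.

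Changes followed transcript abundance in each mutant, and ribosomal protein, glycolytic and other abundant transcripts are best read beside it. The 181 genes at 1000 RPKM or more had median log2 changes of -0.48, -0.48 and -0.63 in sac3∆, R288D and cdk8∆, and the 394 genes at 3 to 10 RPKM had 0.18, 0.18 and 0.46. The 334 genes at 1 to 3 RPKM, which the pseudocount shrinks most, had 0.06, 0.03 and 0.37. Spearman's rho between change and abundance across genes, which are not independent replicates, was -0.364, -0.368 and -0.516. It was 0.0383 between R288D and sac3∆. After quantile normalization, which removes such a trend by construction, it was -0.0288, -0.0336 and -0.0153.

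**Figure D4:**
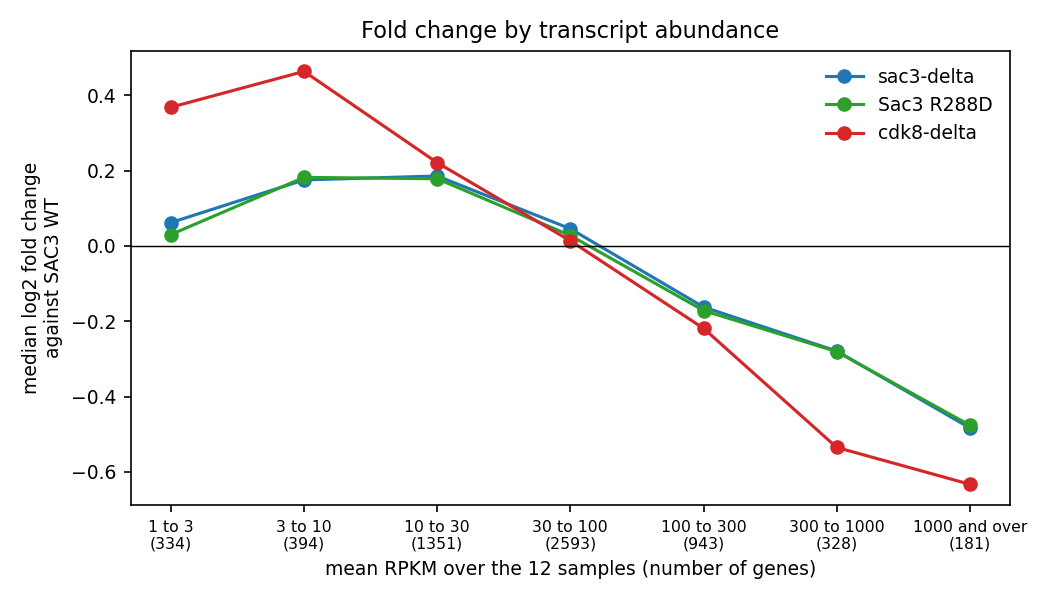
Median log2 change from wild type in sac3∆, R288D and cdk8∆ (vertical axis) in 7 classes of mean RPKM (horizontal axis, 181 to 2593 genes per class). The medians are 0.06, 0.03 and 0.37 at 1 to 3 RPKM (334 genes), and fall from 0.18, 0.18 and 0.46 at 3 to 10 RPKM to -0.48, -0.48 and -0.63 at 1000 RPKM or more.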

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

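In this part the tests of abundance, ribosomal protein and phospholipid patterns were chosen only after the results were seen (the slower-growth test was reworded once, with the same outcome), and the splits of the samples were planned before they were run.

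The following results differ between groups by a direct test of the difference. Genes called in opposite directions, with the difference itself called by limma, numbered 12 between sac3∆ and R288D, 636 between cdk8∆ and R288D, and 609 between sac3∆ and cdk8∆. These were all the genes called in opposite directions. With wild type shared in 1 fit, the difference of such a gene spans both changes. For the pairs with cdk8∆ its call therefore adds no separate support. R288D and sac3∆ differed at 84 genes, SAC3 included. INO1 differed between them by 2.74 on the log2 scale, and 14 phospholipid synthesis genes were higher in R288D.

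Other splits of each 6 samples into 3 and 3 were fitted the same way with limma. With 10 splits, a share under 0.05 cannot be reached. Of these 10 splits, 1 (the real split) gave as many genes as the real count for sac3∆ (3156, highest other 0), R288D (3108, highest other 0) and cdk8∆ (3802, highest other 0) against wild type, and for R288D (3903, highest other 0) and sac3∆ (3924, highest other 0) against cdk8∆. At an unadjusted p under 0.05 the highest other split gave 297, 479, 70, 402 and 121 genes in that order, and the real splits 3493, 3467, 4045, 4100 and 4127. For R288D against sac3∆, 2 of 10 splits gave as many genes as the real 84, the other giving 379. At an unadjusted p under 0.05 the real split gave 683 genes and 2 other splits gave more, 1515 and 1256, so the group labels do not mark the largest division of these 6 samples. The split with 379 set sac3∆ replicates 1 and 2 with R288D replicate 2 against the rest, which points to a structure of these samples beyond their groups. Leaving out sac3∆ replicate 1 gave 53 genes and leaving out R288D replicate 2 gave 468.

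Abundant genes were lower in each mutant than in wild type, and genes at 3 to 30 RPKM higher, with Spearman's rho of -0.364, -0.368 and -0.516 in sac3∆, R288D and cdk8∆. A constant background of reads would add like amounts to scarce and middling genes, but the rise at 10 to 30 RPKM was at least 4.82 times that at 1 to 3 RPKM in each mutant, which argues against it, and within length classes rho stayed at -0.387 or lower, which argues against transcript length. A property of the wild type libraries remains open for the TREX-2 mutants, since R288D and sac3∆ did not differ with abundance (rho 0.0383), but an effect shared by both TREX-2 mutants predicts the same. For cdk8∆ such a property cannot be the whole cause, as both TREX-2 mutants differed from cdk8∆ with abundance (rho of at least 0.205). The scaling inferred from the deposited values differed between groups too. With that scaling undone before the log, a check chosen after the data were seen, rho was -0.336, -0.341 and -0.480, and with RPKM medians set equal -0.378, -0.379 and -0.521.

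Ribosomal protein genes fell in the TREX-2 mutants, with medians of -0.73 and -0.71. The list median differed from that of 278 genes near the 139 members in abundance by -0.53 or more in size. Each matched gene was counted once, so their abundance may lie below that of the members, and the share of the abundance trend is not settled. After quantile normalization the list was still called down in both mutants (limma camera adjusted p = 3.01e-19 in each), a call lost at adjusted p = 0.318 with an estimated correlation. Slower growth with ribosome biogenesis genes falling alike is argued against by the biogenesis medians of -0.02 and 0.01, at least 2.35 SD of their members above the ribosomal proteins. That SD is across genes. Across samples the biogenesis medians ran from -0.08 to 0.07 in sac3∆ and, with mixed sign, from -0.21 to 0.18 in R288D. The ribosomal protein medians ran from -0.79 to -0.65 in sac3∆ and from -0.86 to -0.60 in R288D. A candidate explanation that remains untested is a TREX-2 effect on these genes. In cdk8∆ the list lay -0.17 from genes of like abundance, between the bounds set for the test, so the list and the trend cannot be told apart there.

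Phospholipid synthesis genes were higher in R288D than in sac3∆. A single library is argued against: with each library left out in turn, 10 to 15 of 18 genes were called higher and INO1 stayed between 2.68 and 2.81. A difference in the inositol of the cultures may give the same pattern, as INO1 (2.74) and inositol-regulated genes lead it. The groups and their cultures cannot be told apart, because the cultures were not described separately. The R288D protein itself remains an open explanation.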

How the results depend on the processing

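In this part the limma-voom fit, the fit of genes with an exon length and quantile normalization before camera were chosen after the results were seen.

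Counts against wild type and against cdk8∆ stayed within 1.5 times under each alternative except an added 2-fold threshold, which gave 133 (sac3∆), 128 (R288D) and 487 (cdk8∆) against wild type, 6 for R288D against sac3∆, and 563 (R288D) and 556 (sac3∆) against cdk8∆. Shared calls then numbered 88 (sac3∆ and R288D), 27 (cdk8∆ and R288D) and 32 (sac3∆ and cdk8∆). That threshold removes genes by construction. The 84 genes of R288D against sac3∆ became 17 with only these groups fitted, 829 with array weights and 51 at an adjusted p of 0.01, and the cause was not tested. With only the groups compared fitted, cdk8∆ against wild type went from 3802 to 4186 and R288D against wild type from 3108 to 2588. Replicates varied most in R288D (chi-square per gene between pairs, on recovered reads, 25.5 to 43.3, against 5.72 to 13.5 in cdk8∆). The fit of all 12 samples gives all groups the same spread.

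Leaving out each replicate gave 2788 to 2943 genes for sac3∆, 2730 to 3135 for R288D and 3393 to 3590 for cdk8∆ against wild type. Against cdk8∆ the ranges were 3559 to 3991 (R288D) and 3513 to 3708 (sac3∆). For R288D against sac3∆ it was 53 (without sac3∆ replicate 1) to 468 (without R288D replicate 2). Shared calls ranged from 2350 to 2648 (sac3∆ and R288D), 1271 to 1508 (cdk8∆ and R288D) and 1317 to 1473 (sac3∆ and cdk8∆), and r from 0.854 (without R288D replicate 2) to 0.902, 0.191 to 0.265 and 0.237 to 0.288. With replicate block the counts were 3085, 3009 and 3725 against wild type, 63 for R288D against sac3∆, 3846 and 3879 against cdk8∆, and 2595, 1408 and 1447 shared.

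Quantile normalization, which removes the abundance trend by construction, left 787 shared calls of cdk8∆ and R288D and 848 of sac3∆ and cdk8∆, with r of 0.0424 and 0.0646. Counts for independent calls of these pairs were not computed under that scaling. The r of sac3∆ and R288D moved to 0.846 with a pseudocount of 0.1 and 0.832 with array weights, and the cause was not tested. With an estimated correlation, 6 of 55 list calls held, and 10 list results were called with it after quantile normalization, a setting chosen after the data were seen. Under quantile normalization 39 list results were called, 34 of them called in the same direction as before and 0 in the opposite direction by limma camera. It reversed the direction, without a call, of the TCA cycle list in sac3∆ (adjusted p = 0.933), heat shock genes in R288D (0.733) and ergosterol genes in cdk8∆ (0.899), all by limma camera. In cdk8∆ it also turned ATP2 from -0.61 to 0.070 and LSR1 to 0.46. Of 509 results for named genes, 30 lost their call under at least 1 alternative and 2 reversed. Simulated recovery does not gauge recovery here.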

Other observations

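In this part the zinc list and the gene YNR064C were chosen after their values were seen, and the test on exon length was planned before its result was seen.

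A list of genes linked to the zinc regulator Zap1 was drawn up after ZPS1, ZRT1 and ADH4, which it includes, were seen to change, and no enrichment was tested. Of 14 such genes, 1 rose and 10 fell in sac3∆ (median -0.48), 2 rose and 9 fell in R288D (median -0.33), and 3 rose and 6 fell in cdk8∆ (median -0.05). Without those 3 genes, of 11, 1 rose and 7 fell in sac3∆ (median -0.24), 2 rose and 6 fell in R288D (median -0.24), and 3 rose and 3 fell in cdk8∆ (median 0.02). The vacuolar zinc transporter gene ZRT3 changed by -0.67, -0.57 and 0.02 in that order, IZH2 by -0.95, -0.95 and -0.03, and ADH4 by -1.69, -1.67 and -0.81. ZAP1 itself changed by -0.59, -0.20 and 0.41, and ZRG17 rose by 0.45, 0.45 and 0.22.

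YNR064C, which has no standard symbol, lay at 18.5 ± 0.972 RPKM in sac3∆, 3.67 ± 1.45 in R288D, 10.4 ± 1.34 in cdk8∆ and 1.99 ± 0.598 in wild type, and differed between R288D and sac3∆ by -2.11 ± 0.21 (limma adjusted p = 1.96e-04).

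TREX-2 acts in transcription and export, so genes with long exons were tested for a fall in its mutants. They did not fall: across 5655 protein-coding genes, Spearman's rho between change and exon length was 0.194 in sac3∆ and 0.221 in R288D, and 0.0228 in cdk8∆, where genes are not independent replicates. Given abundance it was 0.159 and 0.190 in the TREX-2 mutants, and in cdk8∆ its sign turned, to -0.0507.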
